A study of Homo sapiens with 4 samples.

How the data were processed

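Gene expression was measured in CCD-Co-18 cells, described in the labels as primary fibroblasts from normal colon mucosa, on 4 Affymetrix HG-U133 Plus 2.0 arrays. This array reads each transcript with sets of short oligonucleotide probes, and each probe set gives 1 value. Per the labels, 2 arrays held RNA of untreated cells and 2 held RNA of cells given TGF-β1, a secreted cytokine, at 5 ng/mL for 8 h. The labels also put each array into pair 1 or pair 2, with 1 untreated and 1 treated array in each pair. Per the labels' protocols, RNA was extracted with TRIZOL, purified on a Qiagen kit, amplified with a whole-transcriptome kit and labelled with biotin.

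The deposited values are on a log2 scale. Per the series' design text, the authors corrected the background by the RMA method, quantile normalized the arrays and summarized probes into probe sets as RMA does, and RMA is also named in the submitters' processing notes. The RMA version is not given in the sources used here. RMA with quantile normalization forces the arrays to nearly the same distribution, so a shift of all transcripts would not be visible. It also compresses changes of dim probe sets, so a fold change from a value near the floor is understated. The values carry no detection calls, and no probe set was called absent. The array medians were 5.20 and 5.21 in untreated cells and 5.23 and 5.21 in treated cells. The number of arrays limits the precision.

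The table held 54675 probe sets. After removal of 62 control probe sets, 54613 were tested. The platform annotation gave 1 gene symbol to 41091 of them, several symbols to 1801, and none to 11721, which are unnamed here. Of the probe sets with 1 symbol, 41037 had a gene ID found in the RefSeq gene table, and 0 symbols needed updating. The 19775 genes were each read at the single-gene probe set with the highest mean over the 4 arrays, a choice that does not use the treatment. Probe sets whose IDs end in _x_at or _s_at can share probes with related transcripts. No genome coordinates are printed because no build is named in the sources used here. Of the genes that the rule for named genes takes, 1 of the preset group and 1 of those with the largest rises are not reported here.

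Treated minus untreated differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 4 arrays, without a term for the pair, because the design text names limma and no pair term. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all 54613 probe sets, and "rose" and "fell" refer to an adjusted p under 0.05. The study's own response criterion, a limma p under 0.05 with at least 2-fold higher signal in treated cells, was counted separately, together with its mirror image for lower signal. The design text does not say whether that p was adjusted, and it was taken as unadjusted. A value given as ± is the standard error of the log2 fold change in this fit unless SD is written, and each group has n = 2. That standard error includes the difference between the pairs. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

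The pair numbers come from the labels, which do not say whether the arrays of a pair shared a culture, day or batch. Deviations from the group means correlated between pair-mates (Pearson r = 0.586 across probe sets), which the main fit does not model. Calls, p-values and ± values come from that unblocked fit unless stated otherwise. A limma fit with the pair as a block was made beside it. The blocked fit leaves 1 residual degree of freedom in place of 2. Arrays of the same group correlated at 0.993 (untreated) and 0.992 (treated), arrays of the same pair at 0.992 and 0.993, and no array was a copy of another.

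There were 31 gene lists, covering TGF-β, BMP, Wnt, Notch and YAP/TAZ signalling, matrix and contractile genes, cytokines and growth factors, the cell cycle, metabolism and cell type markers. Each was tested with limma's camera (preset inter-gene correlation 0.01), two-sided, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, here 2. Few lists could therefore pass it after adjustment, whatever their correlation. Named genes were chosen by a fixed rule. It took a preset group of TGF-β response genes, the 15 genes with the largest rise and the 15 with the largest fall among those past the adjusted threshold with the same direction in both pairs, and, from each list, up to 4 members past the threshold or, where there were none, up to 2 that met the study's criterion in either direction. The lists, the limma, camera and fry tests, the alternatives and this rule were set before the data were examined, and the closing observations name the tests chosen later. List members named outside the rule are said to have been chosen after their values were seen.

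The procedure was tested on simulated data with the spread of these arrays, in 20 runs of 54613 probe sets with 200 changed ones. At an adjusted p under 0.05 it recovered 1.79% of 2-fold, 79.6% of 4-fold and 95.5% of 8-fold changes, and 4.97% of calls were false. The study's criterion was met by 99.8% of 4-fold changes, and by 95 unchanged probe sets in the higher and 94.65 in the lower direction on average. A list of 25 genes shifted by 0.3 on the log2 scale was called in 20 of 20 runs, and 1 of 600 unshifted lists was called. Every value was simulated independently, with the difference between the pairs as part of the random spread. Genes therefore did not vary together, and the list result does not cover lists whose genes do. In the real arrays the difference between the pairs cancels from the fold change. The simulated counts of unchanged probe sets that met the criterion can therefore be too high.

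Alternatives were the pair as a block, each array left out in turn, filters on dim probe sets, array centring, repeated quantile normalization, other variance priors, no variance moderation, other choices of probe set per gene, other thresholds and other list tests. A random pair effect gave no estimate in any probe set. RNA quality was read from control probe sets. The 3′ minus 5′ difference of GAPDH was -0.011 and -0.013 in untreated and -0.025 and -0.032 in treated arrays. For ACTB it was 1.16 and 1.26 in untreated and 0.92 and 1.06 in treated arrays. XIST and Y-linked genes were left out of the gene-level tables.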

Results

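The series asked which transcripts change in colon fibroblasts within 8 h of TGF-β1, and used genes at least 2-fold higher in treated cells as a TGF-β response signature. Untreated CCD-Co-18 fibroblasts (n = 2 arrays) were compared with CCD-Co-18 fibroblasts given 5 ng/mL TGF-β1 (n = 2 arrays). Each array gave 54613 log2 expression values. All values below are RMA values on the log2 scale at 1 probe set per gene.

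TGF-β1 raised ODAPH, a gene known for its role in enamel formation, from 3.99 ± 0.05 (SD, n = 2) to 9.32 ± 0.10 (SD, n = 2), a measured 40.2-fold difference. The untreated value lay at percentile 26.7 of all probe sets and was not shown to be above background, so this fold understates the change if it was not. ESM1, which encodes a secreted proteoglycan of endothelial cells, rose 19.2-fold, and the homeobox gene MEOX1 rose 11.5-fold. The untreated MEOX1 mean was 5.06, at percentile 47.2, and was not shown to be above background either. The interferon-induced gene IFIT1 fell by 2.79 ± 0.21 on the log2 scale to a treated mean of 4.78, at percentile 41.5. NOG, which encodes the BMP antagonist noggin, fell by 2.67 ± 0.13 to a treated mean of 4.07, at percentile 27.8. Neither treated mean was shown to be above background, so that these falls can be understated too. The signalling mediator SMAD3 itself fell by 1.46 ± 0.12. In all, 56 genes rose and 25 fell at an adjusted limma p under 0.05. With the pair as a block in limma, which leaves 1 residual degree of freedom in place of 2, 0 genes passed (smallest adjusted p = 0.106). That fit nevertheless put more probe sets at an unadjusted p under 0.05 (9700, against 4469 without the block). At an adjusted limma p under 0.2 there were 3583 with the block and 766 without it.

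IL11, a cytokine of the IL-6 family, was already bright in untreated cells at 11.58 ± 0.23 (SD, n = 2) and reached 13.77 ± 0.11 (SD, n = 2), a log2 fold change of 2.19 ± 0.16 (adjusted p = 0.0348). IL6 rose by 1.79 ± 0.13 (adjusted p = 0.0348) and LIF by 1.67 ± 0.14 (adjusted p = 0.0362). PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose 6.31-fold, from 9.61 to 12.27 (adjusted p = 0.0205). HBEGF, a ligand of the EGF receptor, rose 4.74-fold. NOX4, which encodes a hydrogen peroxide-producing NADPH oxidase, rose 4.26-fold (adjusted p = 0.0484). WNT2, a Wnt ligand, rose by 1.42 ± 0.12, while the Wnt receptor gene FZD7 fell by 1.52 ± 0.12.

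Other genes with large rises were CAVIN4 (3.54 ± 0.18), which encodes a caveola-associated protein of muscle, the LIM domain gene LMCD1 (3.11 ± 0.13), the long noncoding RNA LINC00312 (2.95 ± 0.21), and GZMK (2.91 ± 0.12), which encodes a granzyme of lymphocytes. CLDN4, which encodes a tight junction claudin, rose by 2.96 ± 0.14 at its brighter probe set, whereas its second probe set gave -0.11. The untreated CLDN4 mean was 4.99, at percentile 45.9. Those of CAVIN4, LINC00312 and GZMK lay at percentiles 53.2, 51.6 and 53.3, and none of these was shown to be above background. The transcription factor gene BHLHE40 rose 5.98-fold, the formin gene DAAM1 5.09-fold, and the thiamine transporter gene SLC19A2 4.85-fold. The epithelial and leukocyte marker lists did not pass the camera test (adjusted p = 0.852 and 0.114), although leukocyte markers passed, in the higher direction, under 2 of 13 other settings (adjusted p = 0.0334 among probe sets at or above the median signal and 0.0396 with the dimmest probe sets, in a range up to 0.237). For CLDN4, the 18 other epithelial markers had a median log2 fold change of -0.02.

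TCF21, a transcription factor of mesenchymal progenitors, fell from 10.37 ± 0.15 (SD, n = 2) to 8.34 ± 0.22 (SD, n = 2), and the transcriptional coregulator CITED2 fell by 1.77 ± 0.16. PTX3, a long pentraxin of innate immunity, fell by 2.16 ± 0.15, and STC2, which encodes stanniocalcin, fell by 1.77 ± 0.14. The adenosine receptor gene ADORA2B fell by 1.96 ± 0.12, and SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 1.76 ± 0.17. PDZRN3 fell by 1.93 ± 0.13, LINC00161 by 1.75 ± 0.15, CAVIN2 by 1.71 ± 0.15, TNFRSF19 by 1.70 ± 0.15, FMN2 by 1.62 ± 0.13, MYBL1 by 1.62 ± 0.14 and CDCA7 by 1.56 ± 0.13. Probe sets of these genes were not all alike. A second CITED2 probe set also fell (-1.52, adjusted p = 0.0478) while a dimmer one gave 0.21, and the dimmer PDZRN3 probe sets gave -0.50 and 0.16. The second LINC00161 probe set gave 0.27, the dimmer MYBL1 probe sets 0.13 and 0.19, and the dimmer FMN2 probe sets -1.26, 0.44 and -0.17, none of them past the threshold. The treated mean of LINC00161 was 3.71, at percentile 21.4 of all probe sets, so its fall was measured against a level not shown to be above background.

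**Figure D1:**
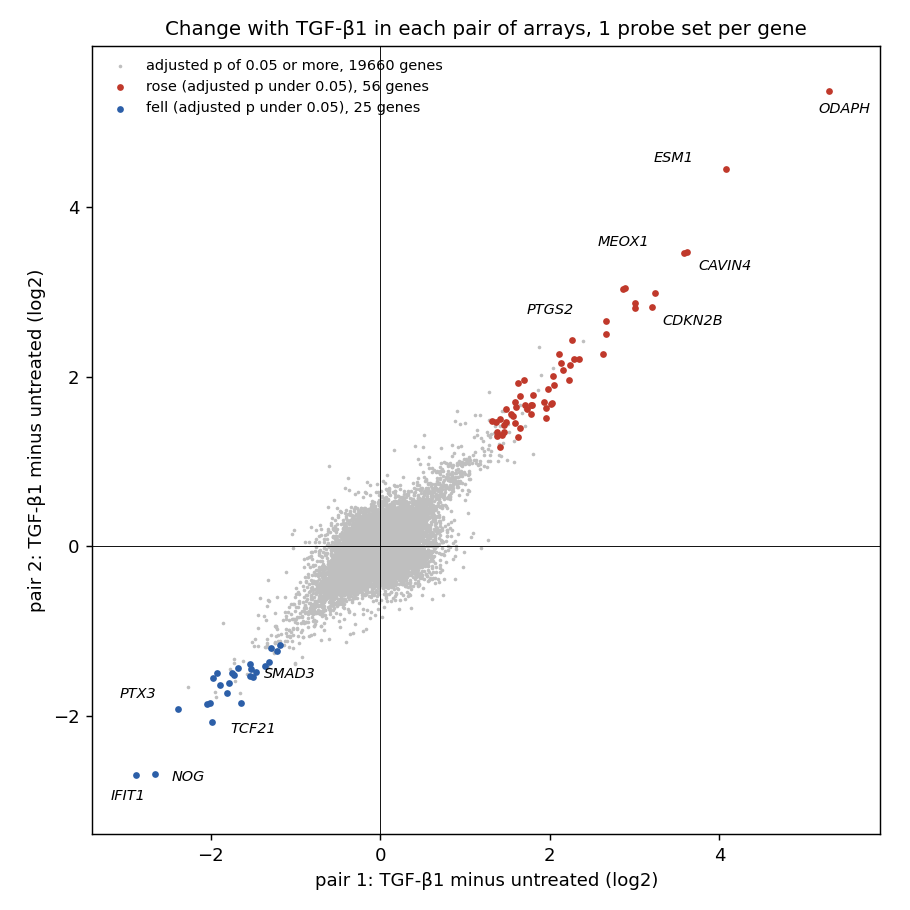
Log2 fold change (TGF-β1 minus untreated) in pair 1 on the horizontal axis and in pair 2 on the vertical axis, 1 point per gene, with 56 genes that rose in red, 25 that fell in blue and genes that did not pass in grey. ODAPH lies at 5.30 and 5.36 and IFIT1 at -2.88 and -2.70, and the points of both pairs correlated across genes (r = 0.709), which are not independent replicates.

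Of 57 genes past the threshold that had more than 1 probe set, 45 had all their probe sets on the same side, and 0 had an opposite probe set at an unadjusted limma p under 0.05. By the study's criterion with its p taken as unadjusted, 285 probe sets (139 genes) were higher and, by its mirror image, 161 probe sets (97 genes) were lower. With an adjusted p in the criterion these were 90 probe sets (56 genes) and 39 probe sets (25 genes). Spread like that of these arrays gave 95 unchanged probe sets on average that met the criterion by chance in the higher direction, and 94.65 in the lower direction. That simulated spread includes the difference between the pairs, which cancels from the fold change because each pair holds both groups. These simulated counts can therefore be too high and do not give the share of chance calls. A crossed split, with 1 array of each group and pair on each side, gave 0 probe sets by the criterion in either direction. It gave 236 at an unadjusted limma p under 0.05. Treatment and pair differences add to the spread in that split, so its counts can be too low. Leaving out any 1 array leaves 1 array in a group and, as with the pair as a block, 1 residual degree of freedom. Such fits have little power at the adjusted threshold and do not show whether a call depends on 1 array. All 81 genes past the threshold kept their direction in each of these fits, which share arrays with the main one.

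Genes of the SMAD feedback and direct TGF-β target list were higher as a group (camera adjusted p = 2.14e-05 and, with an estimated correlation, adjusted p = 0.413). Of its 19 measured members, 3 rose and 0 fell over all probe sets, and 7 were higher and 1 lower when adjusted over the list alone. The cyclin-dependent kinase inhibitor gene CDKN2B rose by 3.01 ± 0.18, PMEPA1, which encodes a membrane inhibitor of TGF-β signalling, by 2.19 ± 0.12, and the adhesion scaffold gene NEDD9 by 1.91 ± 0.18, although the dimmest NEDD9 probe set gave -0.034. The inhibitory SMAD gene SMAD7 (1.04 ± 0.16, adjusted p = 0.139) and its fellow negative regulator SKIL (0.93 ± 0.15, adjusted p = 0.139) were higher in both pairs and did not pass. The pseudoreceptor gene BAMBI had a value of -0.86 ± 0.15 (adjusted p = 0.175), and TGFBI, an abundant matrix gene, 0.21 ± 0.12.

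Among TGF-β ligands, receptors and carriers, TGFB2 rose by 1.34 ± 0.12 and SMAD3 fell, with 2 members higher and 1 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.123). TGFB1 itself measured 0.20 ± 0.29, with 0.33 in pair 1 and 0.07 in pair 2. Its sign turned to -0.04 without untreated replicate 2 and to -0.17 without TGF-β1 replicate 1. Leaving out 1 array unbalances the pairs, so these 2 values also carry the difference between the pairs. In the BMP pathway and ID gene list, NOG was the 1 member of 23 that fell and none rose, 3 were higher and 4 lower adjusted over the list alone, and the list did not pass camera (adjusted p = 0.417) but passed fry (adjusted p = 0.0365). ID1, a direct target of BMP signalling, measured -0.43 ± 0.13 (adjusted p = 0.441).

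**Figure D2:**
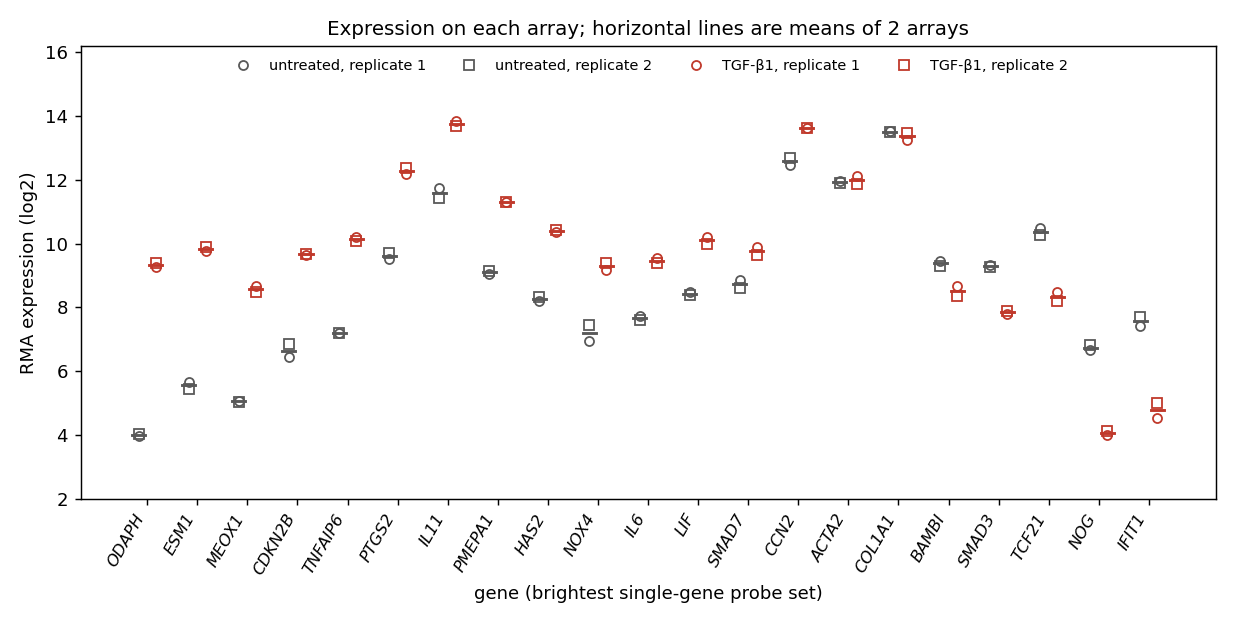
RMA expression (log2) on each of the 4 arrays for 21 named genes, with untreated arrays in grey, TGF-β1 arrays in red, circles for replicate 1, squares for replicate 2 and lines for the means of 2 arrays. PTGS2 moved from 9.61 to 12.27 and TCF21 from 10.37 to 8.34, while ACTA2 stayed between 11.88 and 12.12 on all 4 arrays.

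Matrix glycoprotein and proteoglycan genes were higher as a group (camera adjusted p = 0.00907 and, with an estimated correlation, adjusted p = 0.413). Of 32 measured members 2 rose and 0 fell, with 5 higher and 2 lower adjusted over the list alone. TNFAIP6, a hyaluronan-binding protein, rose by 2.94 ± 0.12 and the hyaluronan synthase gene HAS2 by 2.12 ± 0.12. CCN2, the connective tissue growth factor gene, was 1.05 ± 0.13 higher without passing (adjusted p = 0.0833). The list of matrix proteases and their inhibitors had a camera adjusted p of 0.0126 in the higher direction (adjusted p = 0.413 with an estimated correlation), but the 1 of 26 members past the threshold, the metalloprotease gene ADAMTS1, fell by 1.23 ± 0.11. Adjusted over that list alone, 5 members were higher and 2 lower, and its call was lost without TGF-β1 replicate 2 (adjusted p = 0.0961, with a range of 0.0116 to 0.174 over 14 other settings). For integrins and focal adhesion genes the camera adjusted p was 0.0205 in the higher direction (adjusted p = 0.413 with an estimated correlation). There 1 of 19 rose, the kinase gene NUAK1 by 1.79 ± 0.15, and 4 were higher and 1 lower adjusted over the list alone.

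The collagen genes had a median log2 fold change of -0.03 at 8 h, and the contractile genes, whose products mark myofibroblasts, had a median of 0.06. COL1A1 measured -0.14 ± 0.13, and 0 of 23 collagen genes passed limma's adjusted threshold, with 2 higher and 1 lower at an unadjusted p under 0.05. COL27A1 had the largest collagen value, 1.29 ± 0.15 (adjusted p = 0.0763), and was the 1 collagen higher adjusted over the list alone, but of its 5 probe sets another gave 1.58 (adjusted p = 0.0386) and the dimmest gave -0.35. The collagen list did not pass (camera adjusted p = 0.566), and its negative median differed in sign from its mean (0.06) and from the direction of the test, which was higher. ACTA2, which encodes smooth muscle actin, measured 0.06 ± 0.14 and turned to -0.057 without TGF-β1 replicate 1, and TAGLN measured 0.23 ± 0.18. In the contractile list 0 of 26 genes passed limma's adjusted threshold and 5 were higher and 2 lower at an unadjusted p under 0.05. KANK4, a cytoskeletal regulator, was the 1 member higher adjusted over the list alone (1.36 ± 0.15), from an untreated mean of 4.04 at percentile 27.6 that was not shown to be above background. The list missed the threshold (camera adjusted p = 0.0563) and, with an estimated correlation, had an adjusted p = 0.474. It passed under 8 of 14 other settings, whose adjusted p ran from 0.00185 to 0.416, including without untreated replicate 1 (0.0282) and without TGF-β1 replicate 2 (0.0175).

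Mesenchymal transcription factor genes were higher as a group (camera adjusted p = 0.0126 and, with an estimated correlation, adjusted p = 0.413). MEOX1 rose by 3.52 ± 0.13 and TCF21 fell by 2.03 ± 0.16, 1 member in each direction of 26 measured, and 8 were higher and 4 lower adjusted over the list alone. Immediate early genes were also higher (camera adjusted p = 0.0126 and, with an estimated correlation, adjusted p = 0.413), with 0 of 25 past limma's adjusted threshold, 11 higher and 4 lower at an unadjusted p under 0.05, and 7 higher and 2 lower adjusted over the list alone. JUNB, an AP-1 subunit gene, was 2.07 ± 0.20 higher with an adjusted p of 0.0516. The immediate early list was lost with the pair as a block (adjusted p = 0.0587) and without TGF-β1 replicate 2 (adjusted p = 0.106), in a range of 0.0116 to 0.106 over 14 other settings.

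Growth and angiogenic factor genes were higher as a group (camera adjusted p = 0.0205 and, with an estimated correlation, adjusted p = 0.413). Of 27 measured, 14 were above 0 and 13 below, with a median of 0.05 and a mean of 0.27. The 4 that rose, with 0 that fell, were HBEGF (2.25 ± 0.12), the lipoprotein lipase inhibitor gene ANGPTL4 (1.69 ± 0.12), FGF18 (1.55 ± 0.14) and FGF1 (1.29 ± 0.12). The untreated FGF18 mean was 4.63, at percentile 39.0, and its other probe sets gave at most 0.86, none past the threshold. Adjusted over the list alone, 8 members were higher and 4 lower. The list was lost with the pair as a block (adjusted p = 0.158) and without TGF-β1 replicate 2 (adjusted p = 0.102), in a range of 0.00588 to 0.158 over 14 other settings. Of the 15 measured genes of IL-6 family cytokines and gp130 signalling, IL11, IL6 and LIF were the 3 that rose and 0 fell, with 3 higher and 1 lower adjusted over the list alone. That list passed fry (adjusted p = 0.0365). It did not pass camera (adjusted p = 0.0986), except without TGF-β1 replicate 1 (adjusted p = 0.0319) and among the brightest probe sets (0.0277), in a range up to 0.354 over 14 other settings.

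Cell cycle and DNA replication genes were lower as a group, with the smallest list p (camera adjusted p = 1.14e-06 and, with an estimated correlation, adjusted p = 0.413). Their median log2 fold change was -0.32, and 27 of 30 members were below 0. None of the 30 passed limma's adjusted threshold over all probe sets, 14 had an unadjusted p under 0.05 in the lower direction and 0 in the higher, and 9 were lower adjusted over the list alone. Chosen after their values were seen, the helicase subunit genes MCM2 (-0.76 ± 0.12), MCM3 (-0.62 ± 0.12) and MCM5 (-0.58 ± 0.11) and the cyclin gene CCNE2 (-0.59 ± 0.12) were among those 9. A sign of RNA quality also moved with treatment, as the 3′ minus 5′ difference of ACTB was 1.16 and 1.26 in untreated and 0.92 and 1.06 in treated arrays, lower with TGF-β1 in both pairs. That of GAPDH hardly moved, at -0.011 and -0.013 in untreated and -0.025 and -0.032 in treated arrays.

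Interferon response genes were lower as a group (camera adjusted p = 0.0126 and, with an estimated correlation, adjusted p = 0.415), and 21 of 28 members were below 0. IFIT1 was the 1 member that fell and 0 rose, while 1 was higher and 5 lower adjusted over the list alone. Chosen after its value was seen, IFIH1, a sensor of double-stranded RNA in the same list, went the other way at 1.53 ± 0.17 (adjusted p = 0.0742). The list was lost without TGF-β1 replicate 1 (adjusted p = 0.103, with a range of 0.000133 to 0.103 over 14 other settings).

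**Figure D3:**
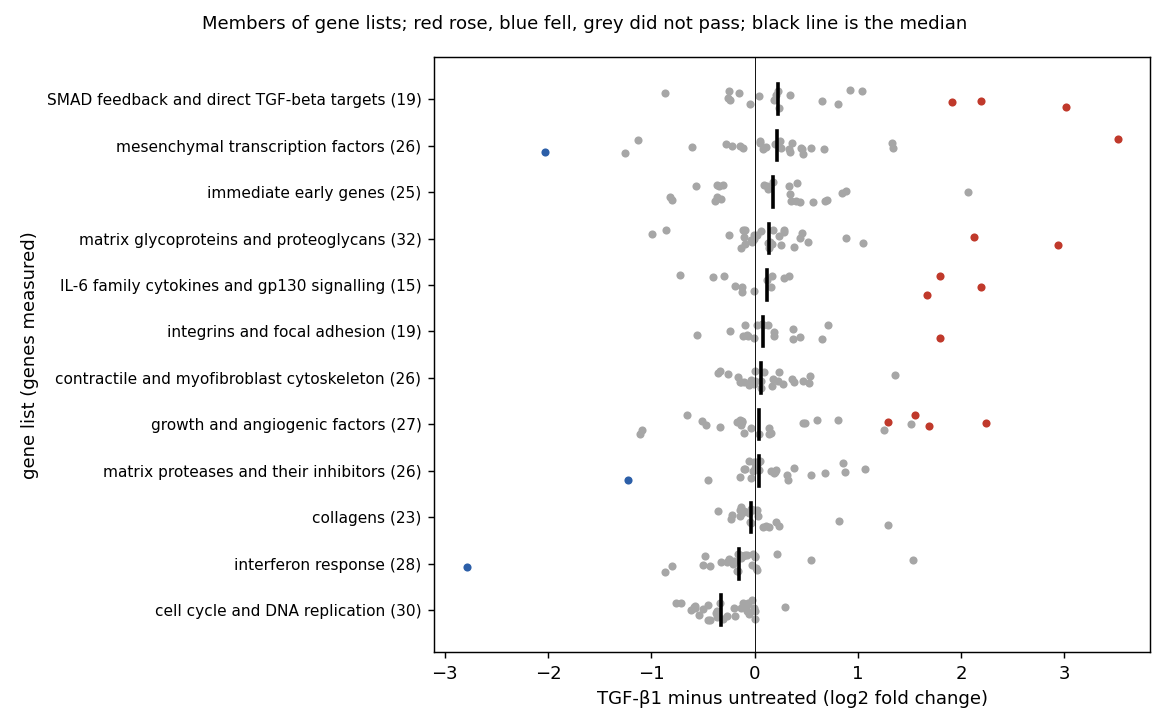
Log2 fold change (TGF-β1 minus untreated) of each measured member of 12 gene lists on the horizontal axis, 1 row per list with the number of genes measured, red for genes that rose, blue for genes that fell, grey for genes that did not pass and a black line for the median. The 30 cell cycle genes lie mostly left of 0 with a median of -0.32, and the 23 collagens lie around a median of -0.03.

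The groups differed in the ACTB 3′ minus 5′ difference (1.16 and 1.26 untreated, 0.92 and 1.06 treated) beside all of these lists. In all, 9 of 31 lists passed camera with the preset correlation of 0.01. With an estimated correlation none passed, and 2 had an unadjusted p under 0.05. Among the lists that passed, the estimate was above 0.01 only for interferon response (0.030) and mesenchymal transcription factors (0.021). It was -0.011 for the cell cycle and -0.031 for SMAD targets, so a higher correlation is not why their p rose. With an estimated correlation camera uses the 2 residual degrees of freedom of these arrays, and with the preset one it uses far more. It therefore had little power after adjustment over 31 lists. The loss of calls does not show that correlation between genes made the results with the preset value. Fry, which tests whether a list's genes move one way on balance, was passed by 10 lists. Integrins (fry adjusted p = 0.0805) and interferon response (0.0584) passed camera but not fry. The BMP, IL-6 family and serine synthesis lists passed fry but not camera. With the pair as a block 7 lists passed camera. Without variance moderation 5 passed, and matrix glycoproteins (adjusted p = 0.0785, with a range from 0.00185 over 14 other settings), integrins (0.0665, range from 0.0122), proteases (0.0880) and growth factors (0.146) did not, and with the dimmest probe set of each gene the mesenchymal transcription factors (0.344, range from 0.00836) and proteases (0.174) did not. Among the other lists, PTGS2 was the 1 member that rose of 30 inflammatory cytokine and chemokine genes (camera adjusted p = 0.611), where 2 were higher and 1 lower adjusted over the list alone. NOX4 was the 1 that rose of 18 NADPH oxidase and antioxidant genes (adjusted p = 0.750), with 2 higher and 1 lower adjusted over the list alone, and the list's median (-0.05) and the test's direction, which was lower, differed in sign from the mean (0.04). In the Wnt pathway WNT2 rose and FZD7 fell of 32 measured (adjusted p = 0.974), with 2 higher and 1 lower adjusted over the list alone, and the median (0.01) and the test's direction, which was higher, differed in sign from the mean (-0.04).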

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

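All alternatives were planned. Over 15 other settings, 571 values of named genes kept direction and side of the threshold, 349 lost the threshold, 12 gained it and 10 turned. The direction of ACTA2 turned without TGF-β1 replicate 1 (-0.057, in a range up to 0.18 over the 4 arrays left out). That of TGFB1 turned without untreated replicate 2 (-0.04) and without TGF-β1 replicate 1 (-0.17, in a range up to 0.56). Within the pairs TGFB1 was higher in both (0.33 and 0.07), and leaving out 1 array mixes the pair difference into the fold change. With the dimmest probe set of each gene, CLDN4 (-0.11), PDZRN3 (0.16), CITED2 (0.21), LINC00161 (0.27), MYBL1 (0.19), NEDD9 (-0.034) and COL27A1 (-0.35) turned, and the cause was not tested. All 81 genes past the threshold passed again, with the same direction, after array centring, repeated quantile normalization and an intensity trend in the prior, as did 71 with a robust prior and 80 of 80 present among probe sets at or above the median signal. The pair as a block gave 0 probe sets higher, 0 lower, 0 genes higher, 0 lower and 0 list members past the threshold in limma. It gave 9700 probe sets at an unadjusted p under 0.05, against 4469 without it, and it changed the call of 2 lists. Its fold changes are those of the unblocked fit by construction, so their signs could not turn, and the 285 probe sets higher by the study's criterion met its p threshold again. The fit has fewer residual degrees of freedom. Leaving out each array in turn leaves 1 array in a group and 1 residual degree of freedom, which gives little power at the adjusted threshold. All 81 genes past the threshold kept their direction in each of these fits. The study's criterion then gave 278 to 375 probe sets higher, 140 to 258 lower (258 without TGF-β1 replicate 2), 132 to 160 genes higher and 88 to 134 lower, and 7 to 10 lists passed. The lone array of a group was assumed to vary like the other group. No variance moderation gave 0 probe sets and 0 genes in each direction, 0 list members and 5 lists, with 4330 probe sets at an unadjusted p under 0.05. Keeping only the brightest probe sets, those above the upper quartile of signal, gave 174 probe sets higher and 86 lower, 101 genes higher and 62 lower, and by the criterion 165 and 83 probe sets and 91 and 57 genes, with fewer probe sets tested. The mean of a gene's probe sets gave 105 genes higher, 49 lower and 42 list members, and 90 and 45 by the criterion. The dimmest probe set gave 27, 10 and 12, and 76 and 44 by the criterion. A test against a 1.5-fold change gave 15 genes higher and 1 lower, an adjusted p under 0.1 gave 105 and 64, and one under 0.01 gave 1 and 0. An adjusted p in the study's criterion left 90 and 39 probe sets and 56 and 25 genes. An estimated correlation left 0 lists by camera, with 2 lists at an unadjusted p under 0.05. The pair as a random effect was not run to a result, because limma's duplicateCorrelation gave no estimate. No detection calls were used, so signal over background limits statements on genes near the floor, such as ODAPH in untreated cells, at percentile 26.7 of all probe sets.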

Other observations

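The tests of other cell types, of cross-hybridisation and of an array ceiling below were chosen after the results they bear on had been seen, and the tests on replication and mitotic genes were set before theirs.

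Markers of glia and interstitial cells of Cajal included the 2 lowest values among the cell type lists. The receptor tyrosine kinase gene KIT measured -1.86 ± 0.29 (limma adjusted p = 0.136) and the transcription factor gene ETV1 -1.53 ± 0.35 (limma adjusted p = 0.298), both lower in both pairs. Of 7 measured markers 0 passed limma's adjusted threshold, 2 had an unadjusted p under 0.05, and the same 2 were lower adjusted over the list alone (camera adjusted p = 0.123). PDPN, which encodes the stromal marker podoplanin, measured 1.00 ± 0.15 (limma adjusted p = 0.132), and 2 of 13 fibroblast markers were higher adjusted over the list alone. The fibroblast list did not pass (camera adjusted p = 0.750), with a median (-0.03) that differed in sign from its mean (0.07) and from the test's direction. The Notch ligand gene JAG1 measured -0.58 ± 0.13 (limma adjusted p = 0.282), and the Notch list had 2 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.221).

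Serine, glycine and proline synthesis genes had a median of -0.18, with 10 of 14 below 0 (camera adjusted p = 0.0767, and 0.0476 to 0.716 over 14 other settings, with a fry adjusted p of 0.0422), and none was past the threshold adjusted over the list alone. The other lists had larger camera adjusted p-values, namely 0.551 for collagen processing, 0.869 for growth factor receptors, 0.950 for IGF binding proteins (0.0396 with the dimmest probe sets, in a range up to 0.996), 0.534 for YAP/TAZ targets, 0.498 for the unfolded protein response, 0.985 for cholesterol synthesis, 0.750 for glycolysis and hypoxia and 0.305 for endothelial markers. In these 8 lists no gene passed limma's threshold over all probe sets. Adjusted over the list alone, 1 IGF binding protein gene was higher and 1 lower, 1 YAP/TAZ target was higher, 1 unfolded protein response gene was higher and 1 lower, and 1 glycolysis gene was higher and 3 lower. The median and mean differed in sign for IGF binding proteins (-0.01 and 0.01) and cholesterol synthesis (-0.09 and 0.02), and for growth factor receptors both were below 0 (-0.03 and -0.02) while the test's direction was higher. In the epithelial list, 1 marker was higher and 1 lower adjusted over the list alone, and the median (-0.02) differed in sign from the mean (0.12). No leukocyte marker passed adjusted over the list alone.

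Splitting the 4 arrays by pair in place of treatment gave 141 probe sets by the study's criterion in either direction and 7816 at an unadjusted limma p under 0.05, against 446 and 4469 for treatment. The adjusted threshold was passed by 0 probe sets when split by pair and by 129 when split by treatment. The pair is therefore a structure of these arrays beside the treatment. Of 11721 unnamed probe sets 10 rose and 3 fell, and of 1801 with several genes 2 rose and 0 fell. By the study's criterion and its mirror image, 35 unnamed probe sets were higher and 16 lower, and 4 with several genes were higher and 1 lower.

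DNA replication genes had lower values with TGF-β1, and mitotic genes less so, although 0 of either kind passed limma's adjusted threshold and the cell cycle list had an adjusted p = 0.413 with an estimated correlation. In that list, 14 G1/S genes had a median of -0.52 (12 at an unadjusted p under 0.05) and 15 G2/M genes -0.08 (2). Outside it, 30 G1/S genes had a median of -0.41, with 29 below 0 and 17 at an unadjusted p under 0.05, and the G1/S median minus that of 25 G2/M genes was -0.247 (95% bootstrap interval -0.371 to -0.130, over genes of these 4 arrays that are not independent). The median of the held-out G1/S genes lay at percentile 0 of 10000 random lists matched on signal, and the held-out G2/M median (-0.16) at percentile 0.29. Quantile normalization removes most of any shift of all genes of like brightness. These percentiles therefore cannot decide whether there was such a shift. They show only that both held-out lists were lower than random genes of like signal, which need not vary together as list members may. A candidate explanation, as a hypothesis, is that fewer treated cells had entered DNA synthesis by 8 h, which no measurement here of the cell cycle itself tests, and differences in cell density or in RNA quality (ACTB 3′ minus 5′, 1.16 and 1.26 untreated, 0.92 and 1.06 treated) stay open and untested.

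CLDN4 and GZMK are better known from epithelial cells and lymphocytes than from fibroblasts. Epithelial cells in the treated dishes would raise the other epithelial markers, whose median over 18 genes was -0.021 (highest 0.29), with EPCAM at 3.74 untreated and 3.47 treated. Leukocytes would raise leukocyte markers, whose median over 14 genes was 0.126 (highest 0.52), with PTPRC at 3.31 and 3.53. These values argue against both sources for rises of 2.96 and 2.91. Cross-hybridisation of the CLDN4 probe set to another transcript that TGF-β1 raises stays open, since the second CLDN4 probe set measured -0.111 at a mean signal of 5.08, below the array medians, where a failed probe set and an unchanged transcript look alike, and no second GZMK probe set was measured.

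Collagens could have been held flat by a ceiling of the array signal, since 8 of them had a brightest probe set at 12 or above. The 10 dimmer probe sets of these 8 genes, at signals of 7 to 11, had a median log2 fold change of 0.067 and an upper quartile of 0.17, which argues against a ceiling as the reason. Of 375 genes with a mean over all 4 arrays of 12 or above, 7 were at least 1.5-fold higher. That mean includes the treated arrays, and IL11 entered from an untreated mean of 11.58, against 13.51 for COL1A1. The count therefore does not test a ceiling at the level of these collagens. A candidate explanation, as a hypothesis, is that collagen transcripts respond after 8 h, and no later time was analysed here.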
